A study of Drosophila melanogaster with 4 samples.

How the data were processed

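Chromatin from nuclei of third-instar wild-type larvae was immunoprecipitated for H3K9me3 in 2 libraries, with 2 input libraries beside them. Per the labels' protocols, nuclei were fixed with formaldehyde, chromatin was sheared by sonication, and antibody-bound fragments were collected on protein A beads. The labels call the antibody a new lot. They number the replicates and do not say whether these came from separate animals or preparations, so standard deviations over the replicates measure the spread between these 2 samples, which may be technical. The p-values come from shifts of clusters along the sequences or from sign flips over the arms and do not measure the spread between samples.

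The authors deposited lists of clusters of significant enrichment: 1 list per ChIP library and 1 list for the replicate set, called the combined list here. The submitters' processing notes name Bowtie 0.12.7 without its role. Positions are on FlyBase release 5 per the file headers. The cluster caller, its threshold and filters, the treatment of reads that match repeats, and the way the replicates were combined are not given in the sources used here. Each cluster has a deposited score whose scale is not stated per the file headers. It was used to rank and filter clusters within a list and, across overlapping clusters, for a correlation.

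Where clusters share the same score to within 1e-06, the steps between neighbouring tied scores above 3 were compared with logarithms of ratios of whole numbers up to 40, to within 5e-06. On the log2 scale 17 of 35 steps matched in replicate 1, 16 of 31 in replicate 2 and 12 of 20 in the combined list, against 0.29%, 0.33% and 0.2% of random steps. On the natural log scale 0 steps matched in each list. On the log10 scale 1 step matched in replicate 1, 1 in replicate 2 and 0 in the combined list. These matching steps have the spacing of log2 ratios of small numbers. The steps that did not match and scores of 3 or less leave the scale open.

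Read totals are not given, so the depth is unknown and no counting interval was computed. The narrowest cluster was 1301 bp in replicate 1, 1302 bp in replicate 2 and 1001 bp in the combined list. The lists may therefore differ in their width limits or in how clusters were called, which was not tested. Such a difference can make coverage, cluster counts and overlap differ between the combined list and the replicates.

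Clusters that ran past a sequence end were clipped to it. There were 4 in replicate 1, 3 in replicate 2 and 6 in the combined list, with an overhang of at most 983 bp. The combined list also holds 3 regions of depletion, which were left out of all comparisons. No list has a cluster on Uextra, which stayed out of all totals. Covered percent is the covered bases over the sequence length in the file headers. Proximal windows are the 2 Mb at the right end of 2L, 3L and X and at the left end of 2R and 3R.

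Overlap was counted at 1 bp or more and tested against 1000 circular shifts of 1 list within each sequence or window, with two-sided p-values. Clusters were assigned to a window by their midpoint for overlap, counts, scores and widths, and coverage was counted by base. Proximal and remaining coverage were compared by an exact two-sided permutation test over the 5 arms. Score correlations used, for each cluster of replicate 1, the cluster of replicate 2 that shared the most bases, and 1000 bootstrap draws gave the 95% interval of the Spearman correlation. The overlap code was tested on simulated data, 20 pairs of lists of 1330 clusters with the replicate 1 widths on the large arms outside the proximal windows. All 20 pairs that shared clusters had p under 0.05, 0 of the unrelated pairs did, and the shares were recovered to rounding error. Shared clusters were exact copies and the others were placed clear of the first list, so this recovery checks the code only. The simulated clusters were scattered at random and tested with fewer shifts. False positives among clumped clusters were therefore not examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

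The groups came from the sample titles. The tests, the processing alternatives and the rule for named items were fixed before the data were examined. That plan did not name the steps between tied scores or the bootstrap interval of the score correlation. Nor did it name the split of combined clusters by replicates overlapped or the widest clusters outside the proximal windows. Other later additions are named where they appear. The rule named members of 9 gene lists (118 genes) that have a coverage value, the 10 widest and the 10 highest-scoring clusters of the combined list on the large arms, and the 10 genes with the most covered bases outside heterochromatin. The gene table used here is on release 6, so its positions were not set against clusters of release 5. The test of genes under clusters was therefore not run, no gene has a coverage value, and the table served for names and chromosomes only. Alternatives varied the required overlap, the score limit, the width minimum, the set of sequences, the joining of clusters within 1000 bp, the proximal window and the lists used.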

Results

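The series measured where trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of heterochromatin, lies in the genome of Drosophila melanogaster larvae. Nuclei of wild-type Oregon-R animals at the third larval instar were crosslinked, and chromatin was immunoprecipitated with an antibody against H3K9me3 and sequenced. The 4 samples were 2 immunoprecipitated (ChIP) libraries and 2 input libraries, each input serving as the background for the ChIP library of the same number. The files analysed here were 3 lists of clusters, which are stretches of significant enrichment called by the authors: 1 per ChIP replicate and 1 combined list for the whole series. The input libraries had no list analysed here, so no group was compared with another. Read numbers were not given in the sources used here, and the depth behind each cluster is therefore unknown.

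Replicate 1 held 3258 clusters over 22.5 Mb and replicate 2 held 3287 clusters over 24.5 Mb. The combined list held 4060 clusters over 29.2 Mb. Clusters lay on 13 sequences of FlyBase release 5: the large arms 2L, 2R, 3L, 3R and X, the small chromosome 4, the heterochromatic scaffolds 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, and U, which gathers unplaced sequence. The median cluster width was 2582 bp in replicate 1, 2731 bp in replicate 2 and 2268 bp in the combined list. The widest clusters measured 156396 bp, 288552 bp and 357995 bp in these lists.

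The question of where the mark lies was answered by the percent of each sequence that clusters covered. Chromosome 4 was covered almost throughout, at 92.7% ± 2.54 (SD, n = 2 replicates, as in all values that follow). The 6 heterochromatic scaffolds together were covered at 80.0% ± 1.58, and U at 65.2% ± 5.43. The large arms outside their centromere-proximal 2 Mb were covered at 3.52% ± 0.466. Over all 13 sequences the coverage was 16.8% ± 1.01.

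Chromosome 4 exceeded the large arms outside the proximal windows 26.5-fold ± 2.79, and the heterochromatic scaffolds exceeded them 22.9-fold ± 2.59. Both differences were many times the spread between the replicates. In the combined list the folds were 15.3 and 13.4. Among the scaffolds, 3LHet reached 88.2% ± 1.36, 3RHet 82.7% ± 1.37, 2RHet 75.6% ± 0.956 and 2LHet 72.2% ± 0.944. XHet, from the X chromosome, was covered at 67.9% ± 5.50. YHet, from the Y chromosome, was the lowest scaffold at 59.4% ± 8.92. YHet was covered at 53.1% in replicate 1, below XHet (64.0%) and U (61.3%), and at 65.7% in replicate 2, again below XHet (71.8%) and U (69.0%). This order depended on the score. With only the clusters at or above each list's median score, XHet was the lowest scaffold at 37.4%, and YHet was at 55.5%.

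Whole arms differed as well. 2R was covered at 10.3% ± 0.365, X at 9.09% ± 1.61, 3L at 7.93% ± 0.305 and 2L at 6.83% ± 0.451, whereas 3R was covered at 1.99% ± 0.225. The difference between 3R and every other large arm was larger than the spread between replicates. The arms were taken as assembled, without the heterochromatic scaffolds. Within each replicate X lay between 3L and 2R, at 7.95% in replicate 1 and 10.2% in replicate 2. This place depended on the list and the score. In the combined list X was the highest large arm at 14.8%, against 12.7% for 2R. With only the upper 50 percent of each list by score, X was at 1.54%, below 2L (3.91%), 3L (5.85%) and 2R (7.62%). Replicate 2 covered more than replicate 1 on each of the 13 sequences. No p-value was computed for these values, because there is no control list and 2 replicates of 1 group. Keeping only the upper 50 percent of each list by score lowered the coverage of the large arms outside the proximal windows to 0.479%, against 77.5% for chromosome 4 and 77.8% for the heterochromatic scaffolds.

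**Figure D1:**
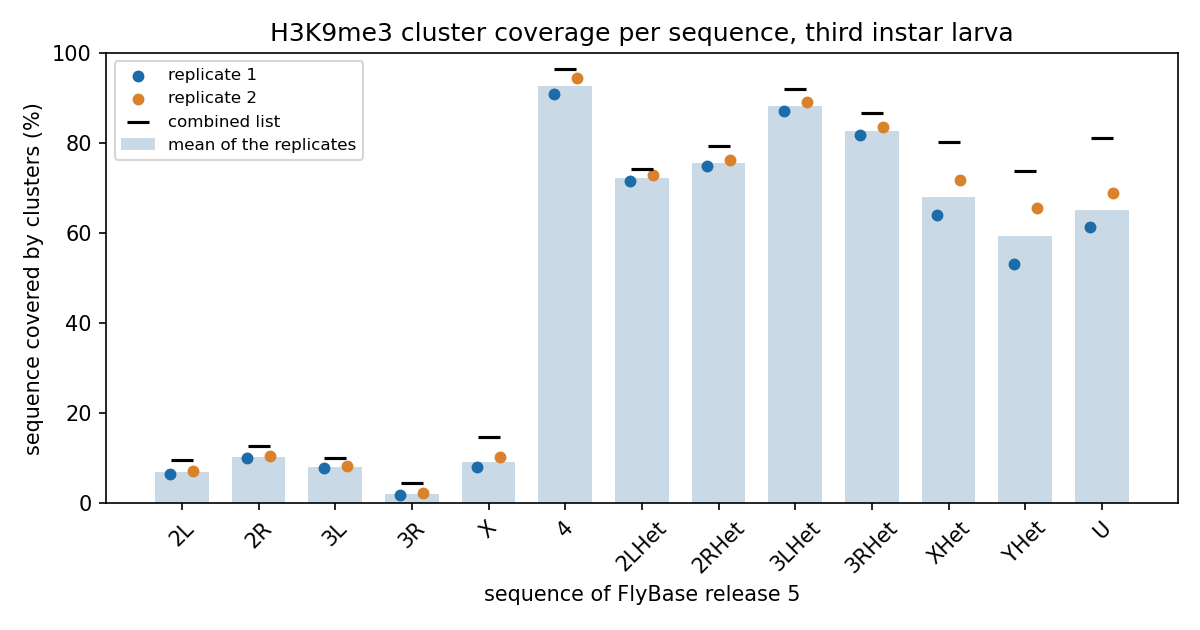
Percent of each of the 13 sequences covered by H3K9me3 clusters: the bars are means of the 2 replicates, the points are the replicates and the dashes are the combined list. Chromosome 4 (92.7%) and the scaffolds (59.4% to 88.2%) stand far above the large arms (1.99% to 10.3%).

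Chromosome 4 carries 80 protein-coding genes in the gene table used for names, which is on release 6. Of the 26 chromosome 4 genes listed before the data were examined, 24 had a matching symbol there, and all 24 were placed on chromosome 4. They include ci, the transcription factor at the end of the Hedgehog pathway, ey, a regulator of eye development, and pan, the transcription factor of the Wingless pathway. Coverage of single genes was not computed, because gene positions of release 5 were not used here.

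Cluster coverage was then compared between the centromere-proximal 2 Mb of each large arm and the rest of the same arm. Coverage was higher in the proximal window on all 5 arms in both replicates. The proximal window of 2R was covered at 76.0% ± 0.932 against 3.42% ± 0.306 in the rest of the arm. On 3L the values were 72.6% ± 0.809 and 2.19% ± 0.261, and on 2L 47.6% ± 2.66 and 2.95% ± 0.240. X followed with 20.4% ± 3.26 against 7.98% ± 1.45. 3R had the lowest proximal coverage, 5.93% ± 0.904 against 1.68% ± 0.173. The windows are ends of the assembled arms, and scaffolds such as 3RHet (82.7%) and XHet (67.9%) lie outside them. How much centromere-proximal sequence each assembled arm holds was not analysed here, so these values do not rank the centromere regions of the chromosomes.

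The mean difference between window and rest was 40.8 percentage points (SD over the 5 arms 31.8). An exact two-sided permutation test that flips the sign of each arm's difference gave p = 0.0625, which is the smallest p that 5 arms allow, so the design cannot pass 0.05. Within each arm the difference was larger than the spread between the replicates.

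**Figure D2:**
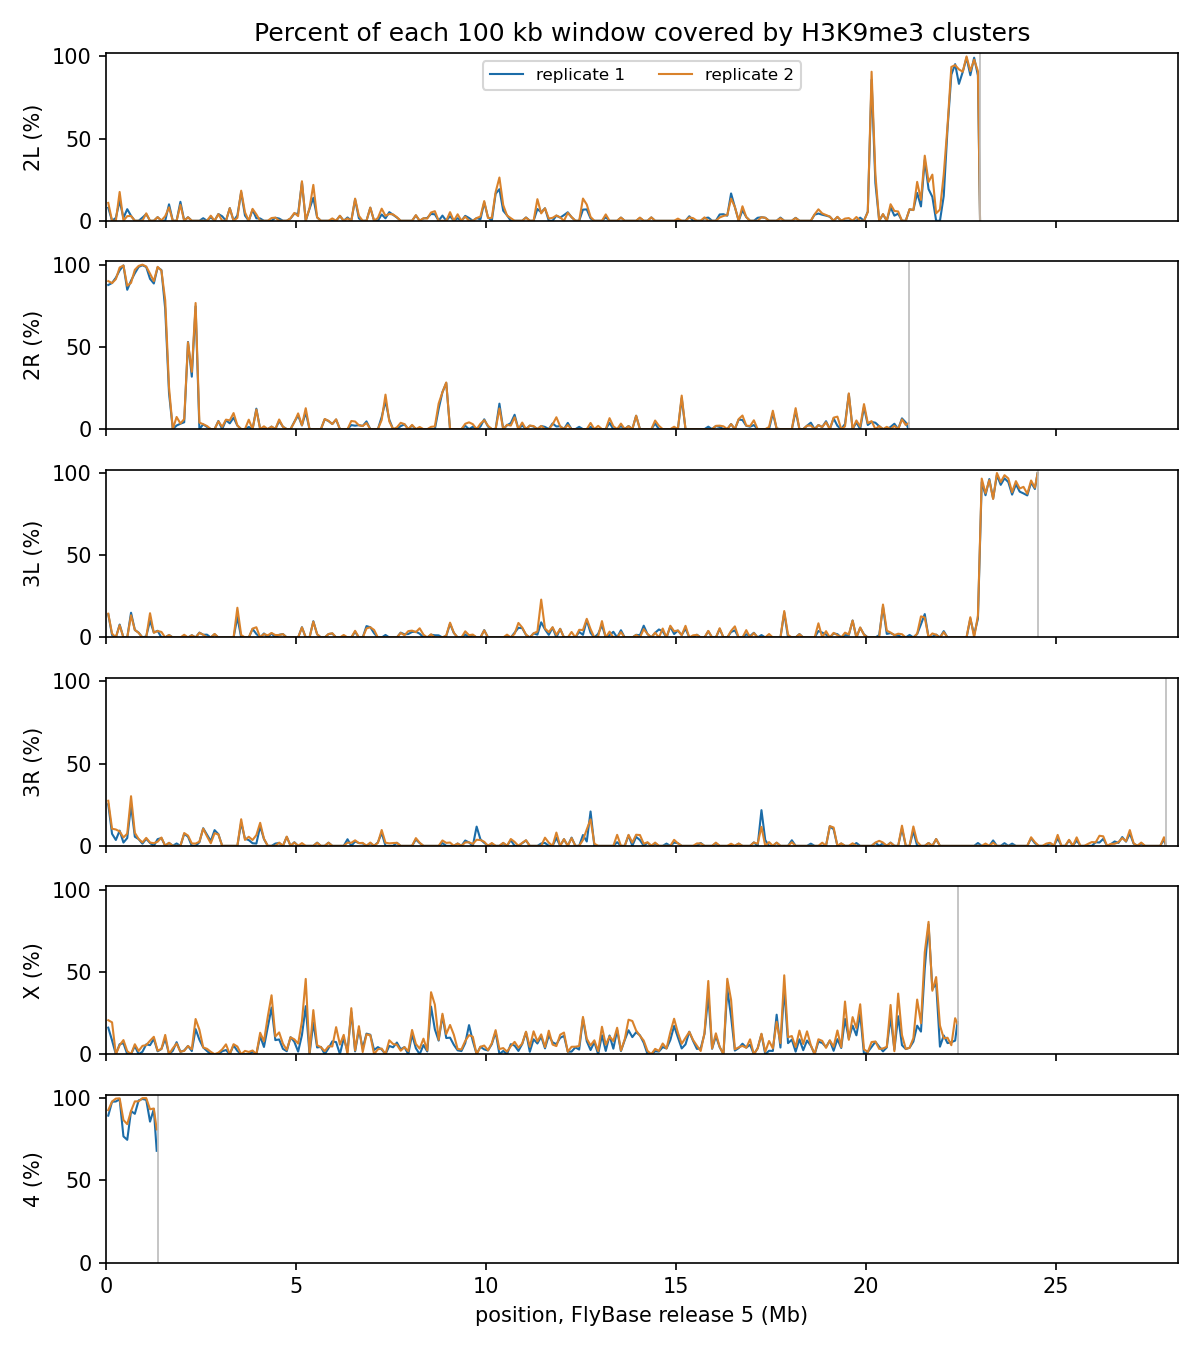
Percent of each 100 kb window covered by clusters along 2L, 2R, 3L, 3R, X and 4, by position in Mb, with 1 line per replicate and a grey line at the end of each sequence. Coverage is near complete toward the right end of 2L (up to 23 Mb), at the right end of 3L, at the left end of 2R and along chromosome 4, and the proximal 2 Mb of 3R stays at 5.93% on average.

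Outside the proximal windows, X carried more clusters than any autosomal arm. Clusters covered 7.98% ± 1.45 of X and 2.49% ± 0.240 of 2L, 2R, 3L and 3R together, a ratio of 3.19 ± 0.274. X held 26.3 clusters per Mb in replicate 1 and 31.2 in replicate 2, against 8.95 and 9.68 on the autosomal arms. The median cluster there was 2057 bp wide with a score of 0.751 on X in replicate 1, and 1953 bp with a score of 0.649 on the autosomal arms. In replicate 2 the median scores were 0.758 and 0.622.

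The ratio depended on the score. Among clusters with scores below 0.4 it was 0.816 in replicate 1 and 1.03 in replicate 2. Among clusters with scores from 0.8 to 1 it was 5.93 and 5.62, and from 1 to 1.5 it was 6.68 and 9.37. Among clusters with scores from 1.5 to 2 it was 1.19 and 1.67, from 2 to 3 it was 2.11 and 1.33, and at 3 or more, on 3 and 4 X clusters, it was 2.00 and 2.11. The comparison of X with the autosomal arms and these score ranges were chosen after the data were seen. Leaving out 1 Mb in place of 2 Mb at the proximal ends brought the ratio over all scores to 2.18, and the upper 50 percent of each list by score brought it to 1.42. That value is the mean of 0.958 in replicate 1, where the direction turned, and 1.88 in replicate 2. The limit was each list's own median score, 1.75 in replicate 1 and 1.43 in replicate 2, and left 18 and 43 X clusters. The replicates are therefore not compared at like scores here.

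**Figure D3:**
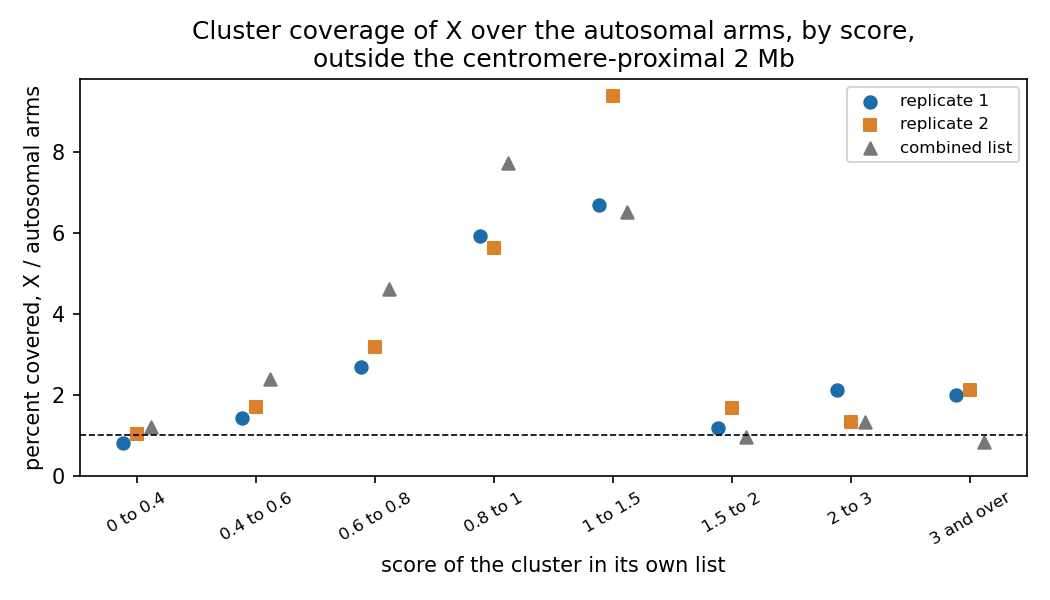
Ratio of the percent of X covered by clusters to the percent of 2L, 2R, 3L and 3R covered, outside the proximal 2 Mb, for clusters of each score range in replicate 1, replicate 2 and the combined list; the dashed line marks a ratio of 1. The ratio is highest for scores from 0.8 to 1.5, where the replicates range from 5.62 to 9.37.

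The replicate lists were compared by overlap. Of the 3258 clusters of replicate 1, 2948 (90.5%) overlapped a cluster of replicate 2 by at least 1 bp. Of the 3287 clusters of replicate 2, 2581 (78.5%) overlapped replicate 1. The Jaccard index, the bases covered in both lists over the bases covered in either, was 0.833. Circular shifts of the list within each sequence gave a mean of 51.2% for replicate 1, 45.3% for replicate 2 and 0.346 for the Jaccard index. The observed values lay above all 1000 shifts (two-sided permutation p = 0.002 for each, the smallest that 1000 shifts can give).

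The index is given by part of the genome beside the mean of the shifts, and differences between parts were not tested. In the heterochromatic scaffolds the Jaccard index was 0.952 (shifts 0.676), on chromosome 4 it was 0.959 (shifts 0.864), in the proximal windows 0.905 (shifts 0.448) and in U 0.793 (shifts 0.481). On the large arms outside the proximal windows it was 0.602, where shifts gave a mean of 0.0248 (two-sided permutation p = 0.002). There 82.6% of the 1330 clusters of replicate 1 overlapped replicate 2, and 69.8% of the 1495 clusters of replicate 2 overlapped replicate 1. Among the arms, 3R had the lowest index, 0.495, and 2R the highest, 0.670. On chromosome 4 and the scaffolds, where most bases are covered, shifted lists also overlapped in most clusters (mean 99.0% and 91.6% for replicate 1), so the count of overlapping clusters says little there. For replicate 2 on chromosome 4, the overlap of 85.3% lay below all shifts (mean 99.1%, lowest 91.2%, two-sided permutation p = 0.002). For replicate 2 it was near the shift mean in the scaffolds (92.6% against 90.8%, two-sided permutation p = 0.388). In U the values were 87.4% and 86.0% (two-sided permutation p = 0.420). The overlap of replicate 1 lay above all shifts in both parts (two-sided permutation p = 0.002 for each). It was 98.8% in the scaffolds (highest shift 95.3%) and 95.8% in U (highest shift 92.2%).

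Scores of overlapping clusters were correlated between the replicates. Across 2948 pairs, the Spearman correlation was 0.900 and the Pearson correlation 0.899. This correlation is across clusters, which are not independent replicates, and no p-value was computed. Within classes, the Spearman correlation was 0.909 in the proximal windows (301 pairs), 0.842 on the large arms outside them (1099 pairs), 0.729 in the heterochromatic scaffolds (402 pairs) and 0.630 on chromosome 4 (51 pairs). In U it was 0.559 across 1095 pairs.

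The combined list was set beside the replicates. It contained 99.8% of the covered bases of replicate 1 and 99.7% of those of replicate 2. In the other direction, 77.0% of its covered bases lay in replicate 1 and 83.7% in replicate 2. Of its 4060 clusters, 1976 overlapped both replicates, 816 overlapped 1 replicate and 1268 overlapped neither. Clusters that overlapped both had a median width of 4892 bp and a median score of 1.21, and those that overlapped neither had a median width of 1345.5 bp and a median score of 0.449. The replicate lists hold no cluster narrower than 1301 bp and 1302 bp, whereas the combined list goes down to 1001 bp. A width limit could therefore add to the clusters that overlapped neither, which was not tested. The score order turned in the heterochromatic scaffolds, where the median was 2.88 for clusters that overlapped neither and 2.33 for those that overlapped both, and in U (2.53 against 2.36).

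On the large arms outside the proximal windows, 1008 of 2589 combined clusters (38.9%) overlapped neither replicate. Their median width was 1329 bp, close to the narrowest width in the replicate lists. In the heterochromatic scaffolds 35 of 253 (13.8%) overlapped neither, with a median width of 1723 bp. The combined list is built on the same libraries and is no independent measurement, so no test was made.

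The 10 widest clusters of the combined list on the large arms all lay in proximal windows, on 2R, 3L and 2L, and both replicates covered each of them by over 50 percent. The widest was 2R from 815203 to 1057306 (242.1 kb, score 2.52), covered at 99.5% in replicate 1 and almost fully in replicate 2. The next were 3L from 23513283 to 23754006 (240.7 kb, score 2.41) and 2R from 1307188 to 1496462 (189.3 kb, score 2.28). The widest on 2L ran from 22576276 to 22710687 (134.4 kb, score 2.52).

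The 10 highest-scoring clusters on the large arms were between 1155 bp and 3144 bp wide (median 2067 bp), with scores from 3.98 to 5.05. The median width of all combined clusters on these arms outside the proximal windows was 1939 bp. Only 1 of them lay in a proximal window. Both replicates covered 2 of them, 3R from 27241169 to 27243488 (score 5.05) and 3R from 3533171 to 3535700 (score 4.40). The cluster on 3R from 26148360 to 26150492 (score 4.66) was covered in replicate 2 at 93.6% and in replicate 1 at 0%. The other 7 had no covered base in either replicate. Genes at these positions were not analysed here.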

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

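The restriction of replicate overlap and score correlation to the large arms outside the proximal windows was chosen after seeing the data. So were the ratio of X to autosomal coverage with its alternatives, and the proximal comparison in the combined list and without X or 3R. Of 122 alternatives over 24 results, 63 had an outcome fixed in advance and say nothing about stability: leaving out 1 of 2 replicates always moves a mean by less than 1 SD, a width minimum of 1000 bp removed no cluster, and the proximal test cannot pass 0.05. Of the other 59, 40 moved a value by more than 1 SD between replicates or out of the bootstrap interval of the score correlation, and 19 did not, of which 16 were overlap tests that stayed on the same side of 0.05. The 59 include coverages under the score limit, which can only fall. They also include coverages in the combined list, which holds 99.8% and 99.7% of the replicates' covered bases and could hardly be lower. For these only the size of the change was open. Replicate overlap ranged from 66.6% (overlap of 50 percent both ways) to 95.8% for replicate 1, above the shifts in each setting. The proximal difference ranged from 29.7 to 56.7 percentage points over windows of 3 Mb and 1 Mb.

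Keeping the upper 50 percent of each list by score changed coverage to 13.6% over all sequences, 0.479% on the large arms outside the proximal windows, 77.5% on chromosome 4 and 77.8% in the scaffolds. It changed the share of replicate bases in the combined list to 99.9%, the share of combined bases in a replicate to 75.3% and the X ratio to 1.42, the mean of 0.958 in replicate 1 and 1.88 in replicate 2. These 2 ratios use each list's own median score as the limit and are not at like scores. The combined list gave coverages of 20.9%, 6.31%, 96.4%, 84.4% and, for U, 81.1%, and an X ratio of 2.82. Windows of 1 Mb and 3 Mb gave X ratios of 2.18 and 3.62. On 2L, 2R, 3L, 3R, 4 and X alone, the shares with the combined list were 99.5% and 71.9%, and the Spearman correlation of scores was 0.876. That correlation was 0.936 with overlap of 50 percent both ways and 0.842 outside the proximal windows. The stricter score limit lowers coverage by construction. A window of 1 Mb leaves 2R from 1 to 2 Mb in the autosomal arms. That stretch was covered at 57.4% in replicate 1 and 59.3% in replicate 2, which raises the autosomal coverage in the X ratio. The cause of the other changes was not tested. For the 11 single sequences, 20 of the 22 alternatives with an open outcome moved coverage by over 1 SD. These 22 were the score limit and the combined list, so the direction was largely fixed and only the size was open. The gene body, transcription start, score and replicate alternatives for genes under clusters were not run, since no gene positions of release 5 were used. No paired analysis was possible because no list of the input libraries was analysed and no groups were compared. Unknown read depth limits every statement on single narrow clusters.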

Other observations

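The borders and uncovered stretches, and the tests of dense stretches and lowest scores on X, of high-scoring clusters and of 3R, were chosen only after the result was seen.

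The densely covered proximal ends stopped at nearly the same place in both replicates. A border was placed where covered bases, counted from the centromere-proximal end, exceeded uncovered bases by the most. On 2L it fell at 22168741 in replicate 1 and 22168692 in replicate 2, on 3L at 22992055 and 22992140, and on 2R at 1629477 and 1635549. Inside these borders, 90.7% to 93.1% of bases were covered. On 3R the same rule gave only 23022 bp and 23049 bp, and on X only 4642 bp and 4612 bp. The rule was applied to the assembled arms only, so 3RHet and XHet were not part of it. In the combined list the border on 2L lay at 22064243, and the stretch on X measured 49300 bp with 56.5% of its bases covered.

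Within chromosome 4, 34 stretches had no cluster in either replicate, 71616 bp in all. The widest ran from 424940 to 437609 (12.7 kb), followed by 506696 to 514391 and 692583 to 700194. In 2RHet the widest such stretch ran from 2648139 to 2761396 (113.3 kb), and 97 stretches together held 756174 bp. Whether these stretches hold unsequenced bases or repeats was not analysed here. Outside the proximal windows, the widest combined clusters were 2L from 20097399 to 20156401 (59.0 kb, score 1.59) and 2R from 2152181 to 2200604 (48.4 kb, score 1.94), and both replicates covered each by at least 91.8%. The 3 depleted regions of the combined list were 1685 bp to 1779 bp wide, with scores between -0.0131 and -0.00396.

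X outside the proximal window had 3.19 times the cluster coverage of the autosomal arms. A few dense stretches are argued against, since the median 1 Mb bin of X was at least 3.07 times the highest autosomal arm median in both replicates, and so are chance calls, since the overlap of X clusters with replicate 2 exceeded the highest shift by 63.5 percentage points. An excess of calls near the lowest scores is also argued against: the ratio was higher at or above the median score of these arms than below it, by at least 2.28. An excess confined to scores below the list's median stays open for the replicates. At or above that median the ratio was 1.88 in replicate 2 and 0.958 in replicate 1, on 43 and 18 X clusters. The medians, 1.43 in replicate 2 and 1.75 in replicate 1, are unlike limits. In the combined list, whose median score is lower at 0.587, the ratio was 4.17 on 368 X clusters. Noisier calls from fewer reads on X cannot be told apart either. The overlap of X in replicate 1 lay 4.33 percentage points above that of 2R (binomial SE 2.98, which treats clusters as independent). Less the mean of the shifts, X lay below 2R (72.1% against 77.4%). In replicate 2 X was at 69.9% against 71.7% on 2R and, less the shifts, lowest of the 5 arms at 56.4%. In each replicate the mean of the shifts was highest on X. X could therefore exceed that mean by less than the other arms could, so the values less the shifts do not rank X among the arms. The overlaps themselves put X above 2R in replicate 1 and below it in replicate 2. No biological explanation was tested.

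The highest scores outside the proximal windows lay on clusters whose median width was not above that of the others. In replicate 1, 9 clusters there scored above 3, with a median width of 1501 bp against 2009 bp for the others, and in replicate 2 there were 15, with 1996 bp against 2068 bp. Chance calls in a single library are argued against for replicate 1, since the share of its clusters that overlapped replicate 2 (6 of 9) exceeded the highest shift by 33.3 percentage points. The scores may rest on few reads: at least 86.7% of these clusters in each replicate shared their exact score with another cluster, against 20.0% of the others in replicate 1 and 16.6% in replicate 2, as ratios of small counts would. No biological explanation was tested.

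On 3R, the combined list was dense from 2 to 3 Mb (54 clusters, against 25 and 20 in the replicates) and from 12 to 13 Mb (75 clusters, against 20 and 20). The ratios of combined to mean replicate counts were 2.4 and 3.75. The other 17 bins with at least 5 clusters per replicate on average had ratios from 1.37 to 4, with a median of 2. Against the highest ratio of the bins with at least 10, the difference was -0.3 for 2 to 3 Mb, where a general increase of calls in the combined list could account for the ratio. For 12 to 13 Mb it was 1.05, and this stays open because 2 of the 17 bins, both with fewer clusters, had higher ratios; no biological explanation was tested.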
